A study of Mus musculus with 7 samples.

How the data were processed

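Single-cell RNA was measured in 4 libraries and antibody-derived tags in 3, from mouse bone marrow labelled C57BL/6, with 1 sample per group. Per the labels' protocols, hind limbs were crushed, cells carrying CD117 were enriched with beads, stained with tagged and fluorescent antibodies and sorted, and 15000 cells per lane went into a 10x Genomics 3′ assay, with RNA and tag libraries sequenced apart. Cell Ranger and the mm10 build are named per the submitters' processing notes. The deposited RNA matrices hold whole numbers that are best read as an expected count per gene and barcode after a subtraction of background RNA. This reading was inferred from the values, since between 7.83% and 9.84% of the stored entries are 0, and from the name SoupX on a deposited table; the step itself is not described in the sources used here. The deposited tag matrices hold a plain count of UMIs per tag and barcode, with 30000 barcodes in each library. The deposited reference centroids of 28 cell types are log2 values, inferred from the data as log2 of counts per 10000 plus 1.

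The matrices list 28692 genes by symbol, of which 27293 (95.1%) matched 1 position in GENCODE M21 on mm10. The wild-type, wild-type GFP, ThPOK-/- and cKit+ libraries held 14137, 11528, 9672 and 11083 barcodes and 227838344, 197703915, 190406608 and 109796691 UMIs in total. Cells were kept with at least 1000 genes and under 10% of UMIs from mitochondrial genes, which kept 77.0%, 70.9%, 71.6% and 80.1% of barcodes. Doublets were not removed in the values reported. Scrublet called 0 in the ThPOK-/- library and 208, 200 and 148 in the wild-type, wild-type GFP and cKit+ libraries, so the alternative without doublets left out the 6% of cells with the highest scores in every library.

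Cell type labels were deposited for the wild-type GFP and cKit+ libraries only. To treat the libraries alike, each kept cell was given the type whose deposited centroid had the highest correlation with its log2 values, scaled to 10000 UMIs. The type was that of the deposited label for 88.0% of 8012 wild-type GFP cells and 85.5% of 8874 cKit+ cells. The centroids are a reference from the cKit+ cells, so the second value is not an independent check. In the wild-type GFP library it was 62.7% for preNeu-2, 75.6% for proNeu-2 and 78.9% for preNeu-1, against 98.5% for preNeu-3 and 97.0% for immNeu. Late neutrophil stages together were 20.7% of wild-type GFP cells by the deposited labels and 20.5% by the assigned ones. Marker genes of the fixed lists were checked in the assigned types with at least 100 cells in a library. In the modified GMP libraries, proNeu and preNeu-1 cells were led by primary granule genes, preNeu-2, preNeu-3 and immNeu cells by late granule genes, MP, cMoP, Mono and MDP cells by monocyte genes, and ERP1, MKP and HSCP cells by erythroid, megakaryocyte and stem cell genes. IG2 cells were also led by primary granule genes, with a median log2 of 0.69, 0.60 and 0.41 in the wild-type, wild-type GFP and ThPOK-/- libraries. ProNeu-1 cells had 1.90, 1.69 and 1.78. Not led by a list of their own name were ERP1 cells of the cKit+ library (mast cell and basophil genes), wild-type MPP4 cells (dendritic cell genes) and Multi-Lin-1 cells, led by mast cell and basophil genes in both wild-type modified GMP libraries, by T and NK cell genes in the ThPOK-/- and by stroma genes in the cKit+ library.

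The reported differences rest on no test between genotypes, because each group has 1 library; an edgeR test that takes the wild-type pair as replicates was run as an alternative only. UMIs were summed over kept cells, or over the kept cells of a type, and divided by the total and multiplied by 1000000 to give counts per 1000000 UMIs (CPM). A gene passed the size rule with at least 10 CPM in at least 1 of the 3 modified GMP libraries and a log2 ratio of at least 1 in size with the same sign against both wild-type libraries. The rule was repeated with each wild-type library singled out. Within cell types it was applied to the 12 types with at least 100 cells in each library, and the mean over these types with equal weight gave the standardised ratio. PreNeu-1, preNeu-3 and immNeu were not among these types, so preNeu-2 alone stood for the late neutrophil stages in that ratio. A library at 0 was set to 3 UMIs for ratios. Genes with at least 20% of stored entries equal to 0 in 1 of the libraries were counted apart, 139 of 7808 genes over all cells. Shares of cell types carry exact Clopper-Pearson intervals, and a share was set apart when its interval lay beyond both wild-type intervals. For the share of cells with a Zbtb7b UMI, cells were also thinned to 5000 UMIs, which gave 3.93%, 6.96% and 0.0728% in the wild-type, wild-type GFP and ThPOK-/- libraries.

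The 28 gene lists, the comparisons and the rules were chosen before the data were examined. A list was described by the median log2 ratio of its members with at least 10 CPM, placed among 10000 random lists of the same size and similar mean expression; it was called apart when it lay beyond the 2.5 or 97.5 percentile on the same side against both wild-type libraries. Genes were named by a rule: Zbtb7b; over all cells up to 12 highest and 12 lowest that also passed after standardisation, ranked by the smaller of the 2 ratios; per cell type the 3 highest and 3 lowest; per list up to 4 members. Predicted genes were counted and left out of this rule, and 2 are named in the closing section after their values were seen, and genes of the sex check were reported apart. Genes outside the rule are said to have been chosen after their values were seen, as were Csf1r and CD44 in their ranges over cell types.

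The 65 tags were compared by their share of all tag UMIs, with a log2 ratio of at least 0.585 (1.5-fold) in size and the same sign against both wild-type libraries, and the 37 that averaged at least 1 UMI per cell in 1 library were also compared within cell types. The panel table lists 67 names for 65 sequences, since CD274 and CD279 share a sequence, as do CD335 and CD357. Tags were set beside their own transcripts with Spearman's rho over the 12 cell types.

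The size rule was tested on simulated data with 7737 genes and 200 of them changed. All simulated libraries were drawn from a single mean profile with a dispersion of 0.02. They had no difference in cell mix, sex or preparation, so their count of unchanged genes past the rule does not carry over to the real libraries. It recovered 34 of 34 genes at a log2 change of -2, 32 of 34 at -1.5, 1 of 33 at -0.5, 0 of 33 at 0.5, 32 of 33 at 1.5 and 33 of 33 at 2, with 0 of 7537 unchanged genes past it. For lists moved by 0.5, a median shift of 0.48 was recovered and 50 of 50 were called apart, as were 9 of 200 lists that were not moved. These lists held random genes and were placed against the wild-type library alone. All 10 changed tags were recovered.

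Alternatives were TMM and DESeq2 scaling, other minimum counts and ratio sizes, all barcodes, the mean over cells, each wild-type library alone, an edgeR quasi-likelihood test with the 2 wild-type libraries as replicates, equal weights per cell type, doublets left out, and, for tags, the centred log ratio. Added after the data were seen were a logistic regression trained on the deposited cKit+ labels, cells with a correlation margin of at least 0.02, a filter at 500 genes and 15% mitochondrial UMIs, cells with at least 5000 UMIs for gene counts, and counts without genes with many stored zeros or without the 3 sparsest types. Deposited map coordinates were left out because no comparison needed them. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.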

Results

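The dataset came from mouse bone marrow and held 7 samples, 1 per group: 4 single-cell RNA libraries and 3 libraries of antibody-derived tags (short DNA barcodes on antibodies, which count surface proteins on the same cells). The RNA libraries were a wild-type, a wild-type GFP and a ThPOK-/- library from a modified GMP gate (a sort aimed at granulocyte-monocyte progenitors), and a wild-type library from a cKit+ gate, the wider population of progenitors that carry the KIT receptor. The 3 tag libraries belonged to the 3 modified GMP samples. The labels do not say what GFP marks, although the deposited cell labels list GFP under the heading Genotype. The wild-type GFP library was used as a second wild-type library of the same gate. Xist, the transcript of the inactive X chromosome, was seen without a Y-linked gene in 98.2% of its cells, while a Y-linked gene without Xist was seen in 88.1% of wild-type and 87.3% of ThPOK-/- cells, so that library also differed from the others in sex. ThPOK, encoded by Zbtb7b, is a zinc finger transcription factor known from the choice of the CD4 T cell fate, and the series title places the question in the development of myeloid cells.

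The wild-type library held 10888 kept cells, the wild-type GFP library 8179, the ThPOK-/- library 6922 and the cKit+ library 8874. These cells carried 214004803, 185953807, 177363708 and 105423630 UMIs (unique molecular identifiers, each standing for 1 captured transcript) in the same order, and a median of 17463, 21922, 24511.5 and 9634.5 UMIs per cell. Tag counts were joined to 10885, 8178 and 6922 of the modified GMP cells, with a median of 1213, 1594.5 and 1227.5 tag UMIs per cell. With 1 library per genotype and gate, no difference below has a replicate check, and the intervals (exact Poisson for counts, exact Clopper-Pearson for shares, 95%) cover counting error only.

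The targeted gene was far lower in the ThPOK-/- library than in either wild-type library of its gate. Zbtb7b (ENSMUSG00000028042, chromosome 3, 89377644 to 89394776, minus strand, mm10) had 36 UMIs there, or 0.203 counts per 1000000 UMIs (CPM; 0.142 to 0.281), against 1814 UMIs and 8.48 CPM (8.09 to 8.88) in the wild-type library and 2691 UMIs and 14.5 (13.9 to 15.03) in the wild-type GFP library. Its level was 41.8-fold and 71.3-fold lower, a log2 ratio of -5.38 (-5.90 to -4.91) and -6.16 (-6.67 to -5.68). A UMI was seen in 12.8% of wild-type, 23.0% of wild-type GFP and 0.506% of ThPOK-/- cells. Pre-B cells of the cKit+ library, taken as background at a median of 3725 UMIs per cell, had one in 0.407%. The ThPOK-/- cells had a median of 24511.5 UMIs, so the 2 shares are not at equal depth. The UMIs left in the ThPOK-/- library were uneven. One was seen in 6.19% of preNeu-1, 6.67% of preNeu-2 and 3.70% of preNeu-3 cells, against 0.327% of proNeu-1 and 1.78% of proNeu-2 cells. The assay counts transcript 3′ ends and the labels do not say which part of the gene was deleted, so a low count shows that the transcript end was rare and does not by itself check the protein.

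In wild-type cells Zbtb7b made up a larger part of the UMIs in the later neutrophil stages. Across the neutrophil series of the wild-type library it went from 7.43 CPM in proNeu-1 cells to 19.3 in proNeu-2, 29.9 in preNeu-1, 36.7 in preNeu-2, 47.6 in preNeu-3 and 60.5 (44.6 to 80.2) in immNeu cells, the immature neutrophils. The wild-type GFP library had 9.53, 24.2, 39.2, 44.4, 55.6 and 77.7 (59.0 to 100.5) in the same stages. Among monocyte stages the wild-type library had 22.6 in common monocyte progenitors (cMoP) and 9.47 in monocytes (Mono), and megakaryocyte progenitors (MKP) had 1.68. The ThPOK-/- library stayed between 0 and 3.14 in all of these types, with 0 UMIs in its 16 immNeu cells (interval 0 to 26.5). From preNeu-1 to immNeu, the share of wild-type cells with a Zbtb7b UMI was 51.2%, 51.4%, 46.0% and 27.4%. Median UMIs per cell fell from 26389 to 5797 over these stages. In the wild-type GFP library the shares were 57.0%, 58.0%, 52.0% and 38.7%. Among wild-type cells thinned to 5000 UMIs, they were 16.5%, 15.1%, 19.6% and 25.3%.

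**Figure D1:**
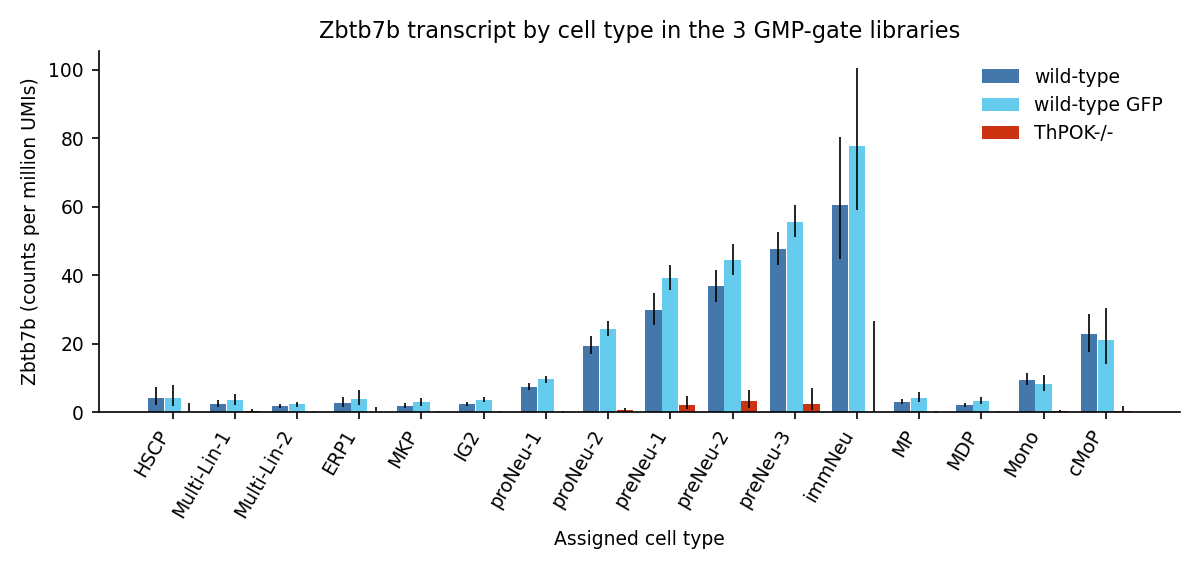
Zbtb7b in CPM (vertical axis, from 0) by assigned cell type (horizontal axis) in the wild-type, wild-type GFP and ThPOK-/- modified GMP libraries (bars), with exact 95% Poisson intervals as lines. Wild-type values go from 7.43 in proNeu-1 to 60.5 in immNeu cells, and the ThPOK-/- value in preNeu-2 cells is 3.14.

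When comparing the cell types of the 3 libraries from the modified GMP gate, late neutrophil stages were rarer and the monocyte series more frequent in the ThPOK-/- library. Late neutrophil stages (preNeu-1 to preNeu-3 and immNeu) made up 4.32% of its cells (3.85 to 4.83), against 11.6% (11.02 to 12.2) of wild-type and 20.5% (19.7 to 21.4) of wild-type GFP cells, which is 0.372 and 0.210 of the wild-type levels. PreNeu-3 was 1.17% against 5.55% and 8.51%, preNeu-2 was 1.52% against 2.93% and 4.98%, and immNeu was 0.231% against 1.24% and 1.45%; preNeu-1, which was led by primary granule genes like proNeu, was 1.4% against 1.90% and 5.60%, with an interval that overlapped the wild-type one. The monocyte series (monocyte progenitors MP, cMoP and Mono) made up 17.3% (16.4 to 18.2) against 11.7% (11.1 to 12.4) and 6.36% (5.84 to 6.91), or 1.47-fold and 2.72-fold more. Within it, MP was 9.87% against 6.39% and 3.29%, and Mono was 5.75% against 4.24% and 2.46%.

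The early neutrophil stages did not separate the ThPOK-/- library from the wild-type pair. ProNeu cells were 17.3% there, between the wild-type 12.3% and the wild-type GFP 24.4%. Cells past the proNeu stage were 19.97% (18.0 to 22.1) of the ThPOK-/- neutrophil series, against 48.6% and 45.7%. The type IG2, a name that the labels do not spell out, was 13.9% against 9.42% and 9.22%. Its cells were led by primary granule genes like proNeu cells, at smaller medians than proNeu-1. The monocyte-dendritic progenitors (MDP) were 8.42% against 7.14% and 5.59%. Stem and multipotent types together were 24.3%, between 20.2% in the wild-type GFP and 31.1% in the wild-type library, and megakaryocyte progenitors were 7.95% against 7.97% and 6.98%. Of the 28 cell types, the ThPOK-/- interval lay above both wild-type intervals in 5 (IG2, MDP, MP, cMoP and Mono) and below both in 3 (preNeu-2, preNeu-3 and immNeu). The same count with the wild-type library singled out gave 4 above and 1 below, and with the wild-type GFP library 5 and 6, so the 2 wild-type libraries also differed from each other. The groupings of stages were chosen after the shares had been seen, and 51.2% of ThPOK-/- cells had a best and a next cell type within 0.02 in correlation; among the other cells alone, the monocyte series was 1.57% against 0.574% and 0.220%.

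**Figure D2:**
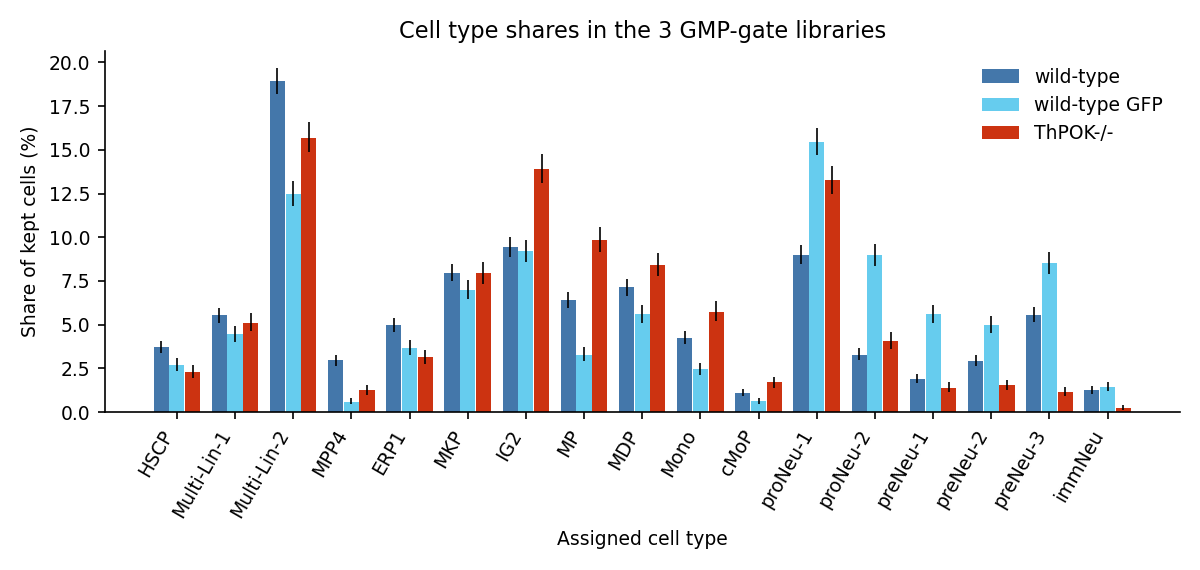
Share of kept cells (percent, vertical axis from 0) by assigned cell type (horizontal axis) in the wild-type, wild-type GFP and ThPOK-/- modified GMP libraries (bars), with exact 95% Clopper-Pearson intervals as lines. PreNeu-3 cells were 5.55%, 8.51% and 1.17%, and MP cells 6.39%, 3.29% and 9.87%.

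Summed over all cells, genes of the late neutrophil granules were lower in the ThPOK-/- library. All 14 measured members of the list of secondary and late granule genes were lower than in both wild-type libraries, with a median log2 ratio of -2.0 against the wild-type and -2.53 against the wild-type GFP library, below every one of 10000 random lists of matched expression. Retnlg, a secreted resistin-like protein, had 3.78 CPM against 45.4 and 39.4, a log2 ratio of -3.59 (-3.70 to -3.47) and -3.38 (-3.50 to -3.27). Mmp8, the neutrophil collagenase, had 1.95 against 17.1 and 18.2, and Mmp9, a gelatinase, 1.82 against 15.6 and 16.9. Ltf, the iron-binding lactotransferrin, had 118 against 636 and 850.0.

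Of 7808 genes tested for size, 65 were at least 2-fold lower in the ThPOK-/- library than in both wild-type libraries and 0 were higher. With the wild-type library singled out the same rule gave 1 higher and 2 lower, and with the wild-type GFP library 18 and 13. Among the 65, named after their values were seen, were Lcn2, an iron-siderophore binding protein (282 CPM against 1122 and 1627), Cd177, a neutrophil surface protein (14.4 against 70.1 and 102.6), Ngp, a granule protein (949 against 3402 and 5517), Cybb, the core of the phagocyte oxidase (64.6 against 195 and 288), and Cxcr2, a chemokine receptor of neutrophils (5.43 against 11.6 and 14.0). For 50 of the 65, at least 20% of the stored entries were 0 in 1 of the libraries, the mark of a subtraction of background RNA, and for 15 they were fewer. When the 12 cell types with at least 100 cells in each library were given equal weight, 62 of the 65 no longer passed. The median of the late granule list was then -0.16 and -0.16 over the same 14 members. It was 0.0014 and 0.013 over the 11 still at 10 CPM, without Retnlg, Mmp8 and Mmp9, which stayed lower. PreNeu-1, preNeu-3 and immNeu, with 97, 81 and 16 ThPOK-/- cells, were under this minimum and left out. Of the late neutrophil stages only preNeu-2 remained, so the smaller ratios cannot be put down to cell mix alone. Of these 62, 6 kept a log2 ratio of -1 or below against both libraries and ended only under the 10 CPM minimum: Zbtb7b (-4.39 for the smaller ratio), Mmp9 (-4.07), Mmp8 (-3.43), AA467197 (-2.15), Fpr2 (-1.47) and Retnlg (-1.33). Erdr1 passed both ways, as did a predicted gene and the X-linked Tsix, which reached the minimum through the wild-type GFP library alone; the predicted gene had 3 UMIs against 8 and 2046. Erdr1 (not placed in the annotation used) had 0 UMIs in the ThPOK-/- library, where 3 UMIs would have been the floor, against 31497 and 25528, and at that floor was at least 8116-fold lower. An edgeR test with the wild-type pair taken as replicates called only Erdr1 at an adjusted p under 0.05, with 1270 genes at an unadjusted p under 0.05, and the count of 65 was 23 at a minimum of 50 CPM and 187 at 1.

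**Figure D3:**
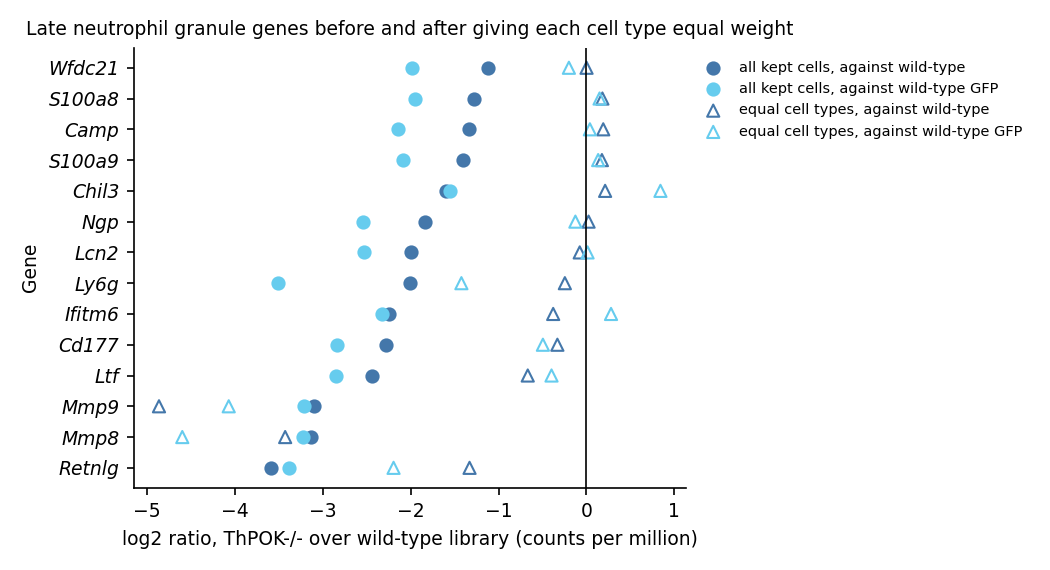
Log2 ratio of CPM in the ThPOK-/- library over each wild-type library (horizontal axis) for the 14 late granule genes (vertical axis). Ratios are summed over all kept cells (filled circles) or give equal weight to the 12 types with at least 100 cells in each library (open triangles). PreNeu-1, preNeu-3 and immNeu are not among these types. All 28 circles lie below 0, and with equal weight Retnlg (-1.33 and -2.19), Mmp8 (-3.43 and -4.60) and Mmp9 (-4.86 and -4.07) stay more than 2-fold lower, each under 10 CPM on that scale.

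Monocyte genes were nearer to the wild-type than to the wild-type GFP level. Of 13 measured genes of the monocyte list, 8 were higher than in both wild-type libraries and 1 was lower, with a median of 0.00 against the wild-type and 0.76 against the wild-type GFP library. Ly86, a partner of the toll-like receptor RP105, had 52.2 CPM against 40.5 and 19.9, and Klf4, a transcription factor of monocytes, 14.1 against 9.64 and 5.79. The 21 myeloid transcription factors had a median of -0.12 and -0.11; Cebpa, which drives granulocyte-monocyte fate, had 58.7 against 42.5 and 45.4, and Fli1 64.3 against 85.0 and 88.0. The 19 growth factor and chemokine receptors had a median of -0.16 and 0.01, with Csf3r, the G-CSF receptor, at 31.6 against 43.9 and 62.7 and Csf2rb, the shared chain of the GM-CSF receptor, at 26.9 against 38.5 and 38.2. None of these 3 lists lay beyond the central 95% of random lists on the same side against both wild-type libraries.

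Of the remaining lists, the 41 genes of the G2 and M phases were below the random lists against both wild-type libraries. Their median was -0.14 and -0.24, with 29 lower in both comparisons; Mki67, the proliferation antigen, had 249 CPM against 328 and 353. TMM scaling moved every log2 ratio by 0.16 against the wild-type and 0.09 against the wild-type GFP library, which turns the sign of the first median to 0.01. With equal weight for the 12 cell types with enough cells, no list lay outside the random range. The primary granule list (12 genes) had a median of 0.13 and -0.25, with Fcnb, a ficolin, at 144 against 224 and 429 and Ctsg, cathepsin G, at 4154 against 2900.4 and 3143. Medians against the wild-type and the wild-type GFP library were -0.58 and 0.02 for stem and multipotent progenitor genes, -0.94 and -0.29 for erythroid, -0.47 and 0.16 for megakaryocyte, -0.52 and -0.07 for dendritic cell, -0.02 and 0.09 for mast cell and basophil, and -0.25 and 0.24 for B lymphoid genes.

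Among lists of general processes, medians were -0.10 and 0.01 for S phase, 0.06 and 0.02 for glycolysis, 0.14 and 0.16 for oxidative phosphorylation, 0.15 and 0.21 for cytosolic ribosomal proteins and 0.04 and 0.23 for mitochondrially encoded genes. They were 0.23 and 0.12 for the unfolded protein response, where Dnajb9, a chaperone of the endoplasmic reticulum, had 26.1 CPM against 16.2 and 19.8, and -0.12 and -0.20 for p53 targets, where Cdkn1a, the cell cycle inhibitor p21, had 12.03 against 8.0 and 6.87. They were -0.24 and 0.18 for the type I interferon response, -0.08 and -0.04 for immediate early and heat shock genes, and 0.03 and 0.15 for MHC class II. Eosinophil genes had 2 measured members, and the lists of T and NK cells, of macrophages, of stroma and of genes tied to ThPOK in T cells had 1 each, too few for a median.

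Within cell types, the ThPOK-/- library differed from both wild-type libraries mainly in genes that were lower, and most of them in the types with the fewest cells. Over the 12 types with at least 100 cells in each library, 48 gene and cell type pairs were at least 2-fold higher and 521 lower. Slc15a2, a transporter of small peptides (ENSMUSG00000022899, chromosome 16, 36750177 to 36784962, minus strand), was lower in all 5 types where it was measured: in Multi-Lin-2, a multilineage progenitor type, it had 3.35 CPM against 19.9 and 14.9 (log2 -2.57, -2.98 to -2.19, and -2.15, -2.58 to -1.74), and in the erythroid progenitors ERP1 7.38 against 33.3 and 28.8. In ERP1 cells, Metrnl, a secreted protein, had 32.2 CPM against 3.95 and 5.76, and Gpr183, a receptor for oxysterols, 31.9 against 7.52 and 7.49. ProNeu-2 cells had Chil3, a chitinase-like protein, at 264 against 99.1 and 97.9, with up to 79.2% of its entries stored as 0, and MKP cells had Mpo, myeloperoxidase, at 12.5 against 75.5 and 73.8, with up to 92.1%.

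Other named genes were spread over the types. In HSCP, the stem cell type, Plekhm3 had 0.746 CPM (1 UMI) against 14.1 and 17.3, the long noncoding RNA Airn 0.746 against 6.71 and 15.7, and Cxcl10, an interferon-induced chemokine, 11.2 against 1.06 and 0. PreNeu-2 cells had Cebpa at 37.6 against 9.81 and 6.74, Prss2, a trypsin, at 12.5 against 2.87 and 1.46, and Apoe, a lipid carrier, at 0 against 58.0 and 47.4. In Multi-Lin-1, Rora, a nuclear receptor, had 10.4 against 5.03 and 3.74. MP cells had Wwc2 at 5.20 against 11.8 and 12.2, Mono cells had Mylip, a ubiquitin ligase, at 4.05 against 10.6 and 9.39, and MDP cells had Gda, guanine deaminase, at 3.42 against 10.1 and 10.8. IG2 cells had Prg2, an eosinophil granule protein, at 1.64 against 32.9 and 7.26. ProNeu-1 cells had Ifitm1 at 2.17 against 12.4 and 7.98. At least 20% of entries were stored as 0 in 1 of the libraries for Cxcl10, Cebpa, Apoe, Mylip, Gda, Prg2 and Ifitm1 in these types, and fewer were for Plekhm3, Airn, Prss2, Rora and Wwc2.

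Erdr1 was lower in all 12 types. Lars2, the mitochondrial leucyl-tRNA synthetase, passed in 7 types at 2.02-fold to 2.67-fold lower, each with at least 20% of its entries stored as 0, and Tex2, named after its values were seen, passed in 6 at 2.01-fold to 2.42-fold lower, 1 of them with as many stored zeros. HSCP, ERP1 and preNeu-2, with 158, 216 and 105 ThPOK-/- cells, gave most of the pairs; without them 5 were higher and 104 lower. Counting error alone, drawn 20 times, gave a mean of 9.8 higher and 33.3 lower over the 12 types, and cell types from a logistic regression gave 295 higher and 765 lower. The same rule gave 98 higher and 54 lower for the wild-type library and 268 and 193 for the wild-type GFP library.

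Gene lists within types showed the S phase and primary granule genes apart from random lists in several types. Each list was placed in up to 12 types and no correction was made for the number of placements. Some calls can therefore arise without a shift. In the simulated data 9 of 200 lists that were not moved were called apart against the wild-type library alone. S phase genes were lower in proNeu-1 cells (median log2 -0.29 and -0.23, with 25 of 30 lower in both comparisons), in proNeu-2 cells (-0.28 and -0.29, with 24 of 30) and in HSCP cells (-0.30 and -0.22). Primary granule genes were lower in MKP (-1.58 and -1.31), Multi-Lin-1 (-0.44 and -0.41), Multi-Lin-2 (-0.35 and -0.53), MDP (-0.30 and -0.36) and Mono cells (-0.14 and -0.23). Entries stored as 0 were more frequent in the ThPOK-/- library for Mpo in MKP (92.1% against 78.0% and 75.8%) and in Multi-Lin-2 cells (29.2% against 13.5% and 15.1%), and for Elane, neutrophil elastase, in Multi-Lin-1 cells (96.5% against 91.8% and 90.5%). Nuclear genes of oxidative phosphorylation were higher in 4 types (IG2, MP, proNeu-1 and proNeu-2), with medians of 0.06 to 0.14. Among the 2581 genes with a mean of at least 50 CPM, the fifth with the shortest transcripts, by median annotated length, had a median of 0.08 and 0.12 over all cells. The fifth with the longest transcripts had -0.15 and -0.11, so small shifts of lists in either direction were not separated from transcript length. Myeloid transcription factors were lower in Multi-Lin-2 (-0.25 and -0.24), and the monocyte list was lower in MDP cells (-0.17 and -0.25). A shift of the size that TMM gave over all cells would turn the sign of the Mono value against the wild-type library. Also beyond the random lists were stem cell genes (lower) and G2 and M phase genes (higher) in ERP1, receptors (lower) in Multi-Lin-2, monocyte and late granule genes (lower) in Multi-Lin-1, interferon and ribosomal genes (lower) and primary granule genes (higher) in preNeu-2, and myeloid transcription factors (lower) and immediate early genes (higher) in MDP cells. Csf1r, the M-CSF receptor, was lower than in both wild-type libraries in all 4 types where it was measured, with a log2 ratio of -0.69 to -0.21 against the wild-type and -0.51 to -0.26 against the wild-type GFP library. The CD115 tag of the same protein was higher than in both in 7 of 12 types and lower in 0, past the 1.5-fold rule in 1. The transcript and the tag were counted over unlike sets of types, so these counts do not show that they moved in opposite directions.

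On the cell surface, tags of granulocyte proteins took a smaller share of the tag counts in the ThPOK-/- library. Gr-1, an antibody to Ly-6G and Ly-6C, was 0.822% of tag UMIs against 1.60% in the wild-type and 3.35% in the wild-type GFP library, a log2 ratio of -0.96 and -2.03. CD11b, the integrin chain encoded by Itgam, was 0.666% against 1.12% and 2.04% (-0.75 and -1.62), and Ly6G, a neutrophil marker, was 0.0667% against 0.102% and 0.358% (-0.61 and -2.42). FceRIa, the IgE receptor of mast cells and basophils, was 0.163% against 0.0761% and 0.0304% (1.10 and 2.43), and CD4, the T helper coreceptor, was 0.333% against 0.222% and 0.171% (0.59 and 0.96). These 5 of the 65 tags passed the 1.5-fold rule, and each averaged at least 1 UMI per cell in 1 of the libraries, as 37 tags did. The rule gave 1 higher and 3 lower with the wild-type library singled out and 7 and 9 with the wild-type GFP library.

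With equal weight for the same 12 cell types, which leave out preNeu-1, preNeu-3 and immNeu, the 3 granulocyte tags no longer passed. Against the wild-type library Gr-1 had a log2 ratio of -0.12, CD11b 0.00 and Ly6G 0.10. Against the wild-type GFP library they had -1.03, -0.59 and -1.37. Gr-1 and CD11b were lower than in both in 10 of the 12 types, past the rule in 0. CD4 and FceRIa still passed, together with CD11c, CD23 and CD197, which averaged under 1 UMI per cell; under a centred log ratio per cell only CD38 passed, and lower. The CD4 tag was higher than in both in 11 of the 12 types and past the rule in 7, as in MKP cells at 0.442% against 0.210% and 0.20%, and the FceRIa tag was higher in 10 and past the rule in 6, as in Multi-Lin-1 cells at 0.268% against 0.0896% and 0.0334%. CD4 stayed a small part of all tags, and across cell types its tag did not follow the Cd4 transcript (Spearman rho -0.18, 0.01 and 0.46 in the wild-type, wild-type GFP and ThPOK-/- library). CD44, an adhesion receptor, was lower in all 12 types, by less than the 1.5-fold rule. The panel has no isotype control tags, so the level of unspecific binding is not known.

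**Figure D4:**
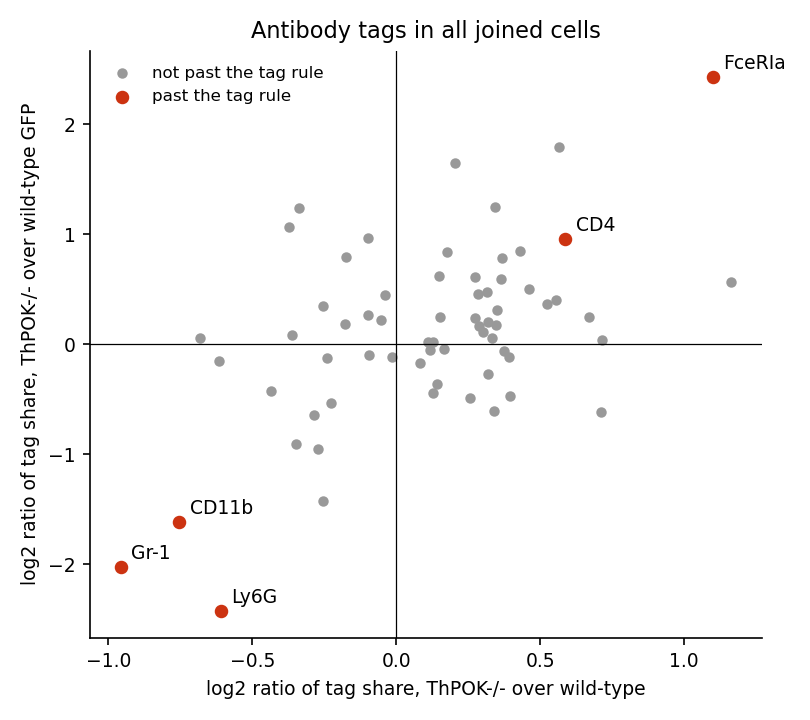
Log2 ratio of the tag share in the ThPOK-/- library over the wild-type library (horizontal axis) and over the wild-type GFP library (vertical axis), 1 point per tag for all 65 tags. The 5 tags past the size rule are in red and named, from Gr-1 at -0.96 and -2.03 to FceRIa at 1.10 and 2.43.

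When tags were set beside the transcripts of the same proteins across the 12 cell types, most followed them. Of 32 tags, 22 had a Spearman rho of at least 0.5 in all 3 libraries, as a description across types and without a test. Of the tags past the 1.5-fold rule, CD11b was among the 22 (0.80, 0.95 and 0.73 in the wild-type, wild-type GFP and ThPOK-/- library). FceRIa (0.59, 0.25 and 0.56), Ly6G (0.18, 0.64 and 0.48) and CD4 were not, and Gr-1 was not compared. CD44 was not among the 22 either (0.08, 0.28 and 0.13). CD115 and its gene Csf1r had 0.89, 0.95 and 0.93, and CD135 and Flt3, a receptor of early progenitors, had 0.93, 0.91 and 0.87. F4/80 and Adgre1, a macrophage receptor, ran opposite at -0.88, -0.77 and -0.62.

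When comparing the 2 wild-type gates, the cKit+ library held B lineage cells and later erythroid stages that were 0 or rare in the modified GMP library. Genes of the B lymphoid list were higher in the cKit+ library by a median log2 of 6.75 over 9 measured genes, and erythroid genes by 3.69 over 11. Vpreb1, part of the pre-B cell receptor, had 151 CPM against 1.41 (107-fold), Hba-a1, a globin, 469 against 1.77 (265-fold), and Klf1, an erythroid transcription factor, 88.6 against 6.89 (12.9-fold). Late granule genes were also higher in the cKit+ library, by a median of 1.63, with all 14 more than 2-fold higher; Camp, the cathelicidin, had 18175 against 4882. The erythroid stages ERP3 and ERP4 were 6.34% and 1.79% of cKit+ cells, against 0.0367% and 0.00918%. Pre-B cells were 8.32% of cKit+ cells and 0 of the modified GMP cells, and late neutrophil stages were 36.4% against 11.6%.

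Genes of early progenitors were higher in the modified GMP gate. Stem and multipotent progenitor genes were lower in the cKit+ library by a median log2 of -1.37, monocyte genes by -0.79, mast cell and basophil genes by -0.79 and primary granule genes by -0.52. Cd34, a progenitor surface protein, had 76.2 CPM in the cKit+ library against 206 (log2 -1.43), Kit 74.7 against 159 (-1.09) and Mpo 2019 against 5123 (-1.34). Medians were 2.32 for T and NK cell genes (3 measured), 5.4 for genes tied to ThPOK in T cells (4 measured), 0.45 for dendritic cell and -0.90 for megakaryocyte genes (3 measured). They were 0.81 for MHC class II, 0.61 for immediate early, -0.64 for myeloid transcription factor and -0.48 for receptor genes. They were 0.17 for S phase, 0.28 for G2 and M phase, -0.25 for interferon, -0.16 for glycolysis, -0.01 for oxidative phosphorylation, 0.35 for p53 targets, -0.36 for the unfolded protein response, -0.27 for ribosomal proteins and -0.36 for mitochondrially encoded genes. These gates differ in 1 library each, and the cell types were defined by the authors on the cKit+ cells.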

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

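Of the tests below, those on all barcodes, on the CD11b and Gr-1 tags, on the spread between the wild-type libraries, on length within cell types and on single genes that differ between the wild-type libraries were chosen only after the result was seen.

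Tag counts that no comparison used were looked at because they lie outside the main measurement. Unmapped tag UMIs were 2.56% of those in the joined wild-type cells, 2.19% in the wild-type GFP cells and 2.82% in the ThPOK-/- cells. Tag UMIs in barcodes outside the RNA barcodes were 7.58%, 9.0% and 9.48% of all tag UMIs in the same order.

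Fewer late neutrophil cells were found in the ThPOK-/- library. A loss of these cells in the filter on genes and mitochondrial UMIs is argued against by the share over all deposited barcodes, which was 3.17% (2.83 to 3.54) against 10.6% and 22.8%. A misplacement by the background subtraction or by the cell type assignment is argued against by the tags, which take no part in either. Cells with at least 5% of their tag UMIs from CD11b and Gr-1 were 2.74% (2.37 to 3.16) against 9.16% and 18.4%. The size of this drop also depends on the tag level per cell. Of the assigned late neutrophil cells, 60.5% reached the 5% in the ThPOK-/- library, against 75.3% and 82.3%. Of all other cells 0.136% did, against 0.468% and 1.86%. A difference in animal, sort or preparation cannot be told apart from the genotype, because the wild-type libraries differ 1.77-fold from each other and the ThPOK-/- library 2.69-fold from the nearer of them, with no second library of either group. A role of ThPOK in the passage to late neutrophil stages is a candidate explanation that stays untested beside it. Wild-type cells had more Zbtb7b in CPM at these stages than at the early ones.

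Longer transcripts were lower in the ThPOK-/- library. Length was the median over the annotated transcripts of a gene. Over 2581 genes, Spearman's rho of the log2 ratio with it was -0.33 against the wild-type and -0.28 against the wild-type GFP library. Between the wild-type libraries it was 0.03 over all cells and -0.04 to 0.19 within cell types. With the longest annotated transcript, these values were -0.51, -0.42, 0.01 and -0.03 to 0.30. With the span of the gene, they were -0.44, -0.38, 0.02 and -0.07 to 0.25. Genes are not independent replicates. The values below use the median length. Another mix of cell types is argued against by the same trend inside every one of the 12 types, the weakest at -0.19, and background subtraction by -0.22 over the 645 genes with few stored zeros. A difference in library preparation cannot be told apart from the genotype, since only 1 ThPOK-/- library exists; between the wild-type cKit+ and modified GMP libraries, 2 of 17 cell types reached 0.2 in size. No biological explanation was tested.

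Erdr1 had 0 UMIs in the ThPOK-/- library. Background subtraction is argued against by the stored entries, zeros included: 0.433% (0.293 to 0.618) of ThPOK-/- cells had one, against 82.1% of wild-type cells. A difference between animals at single genes whatever their genotype is a candidate explanation that the data leave open, because 2 genes, Gm5900 and Gm10093, differed as uniformly between the 2 wild-type libraries, in all 12 cell types. These 2 libraries also differ in sex and in the GFP label, so they are not a comparison within a single genotype and sex. The labels give C57BL/6 for every sample, and whether the allele at Erdr1 itself differs was not tested.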

How the results depend on the processing

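The alternatives chosen only after the result was seen are logistic regression, clear margin, all barcodes for shares, lists and the gate, the wider filter, at least 5000 UMIs for gene counts, doublets left out beyond gene counts and shares, and the counts without genes with many stored zeros or without 3 cell types, and the equal-weight median over all 14 granule genes. No paired analysis was possible because each group has 1 sample. Of 94 alternative values, 66 planned, 40 stayed close to the reported value, 53 moved and 1 reversed, and the cause was not tested unless a filter itself gives it. The 65 genes over all cells were 46 under TMM and 46 under DESeq2 scaling, all of them among the 65, and between 57 and 97 with all barcodes, the mean over cells, doublets left out, the wider filter, deeper cells or the wild-type library alone. They were 23 with 50 CPM and 187 (3 higher) with 1, which changes the genes tested, 231 (2 higher) at 1.5-fold, 169 (16 higher) against the wild-type GFP library alone, 15 without genes with many stored zeros and 4 with equal weight per cell type. EdgeR, with the wild-type libraries as replicates, called 1 gene, Erdr1, at an adjusted p under 0.05, with 1270 of 7808 at an unadjusted p under 0.05. The 4 standardised genes were 15 under logistic regression. The 569 pairs within cell types were 60 with 50 CPM, 1060 under logistic regression (295 higher), 268 without genes with many stored zeros and 109 without HSCP, ERP1 and preNeu-2. Late neutrophil cells of the ThPOK-/- library were 3.17% over all barcodes and 5.39% with a clear margin, and the monocyte series 14.8% under logistic regression and 1.57% with a clear margin, each on the same side of both wild-type libraries. The late granule median of -2.0 was -1.85 under TMM, -1.89 without doublets and, with equal weight per cell type, -0.16 over the same 14 genes and 0.0014 over the 11 still at 10 CPM (without Retnlg, Mmp8 and Mmp9, which stayed lower); the -2.53 against the wild-type GFP library was -0.16 and 0.013. The 5 tags were 1 under the centred log ratio (CD38, lower) and 1 at a log2 of 1 (FceRIa), and the Ly6G tag against the wild-type library reversed from -0.61 to 0.10 with equal weight, while against the wild-type GFP library it was -1.37. Zbtb7b, the B lymphoid gate median and the gene counts, shares and Zbtb7b ratio rerun under the wider filter stayed close. Of the planned choices, 2 were not run as alternatives: the centroid assignment became the reported one, since deposited labels cover only 2 libraries, and isotype scaling had no isotype tags; the tag and transcript comparison had no alternative. Of the 12 types, HSCP had the most genes past the rule from counting error alone, a mean of 8.4 higher and 27.4 lower.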

Other observations

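The test on genes around Zbtb7b was written before its result was seen, and the single genes and tags named here were chosen after their values were seen. Several genes differed from both wild-type libraries in the same direction in many cell types. Ankrd28, a regulatory subunit of a protein phosphatase, was lower in all 12 types, with a log2 ratio of -1.23 to -0.61 against the wild-type and -1.25 to -0.57 against the wild-type GFP library. Serpinf1, a secreted serpin, was higher in all 9 types where it was measured, and Cdkn1a in all 5, with 0.58 to 1.75 against the wild-type and 0.31 to 1.39 against the wild-type GFP library. Cebpa was higher in 7 of 10 types and lower in 0. Csf3r, a receptor, was lower in 10 of 11 types. Among primary granule genes, Mpo was lower in 11 of 12 types and Ctsg higher in 9 of 10, so Mpo and Ctsg did not move together. In the remaining type Ctsg had a log2 ratio of -3.42 against the wild-type library. Most of these types are not neutrophil stages, and Mpo had more entries stored as 0 in ThPOK-/- MKP and Multi-Lin-2 cells, as given above.

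The libraries also differed in sex and at single genes. The wild-type and ThPOK-/- libraries had no Xist UMIs, and a Y-linked gene without Xist was seen in 88.1% and 87.3% of their cells, while 98.2% of wild-type GFP cells had Xist without a Y-linked gene, so the wild-type GFP library reads as female and the other 2 as male. In the cKit+ library, 23.1% of cells had Xist alone and 40.2% a Y-linked gene alone, which reads as cells of both sexes. Ly6c1, a surface protein, had 42.2 CPM in the wild-type GFP library against 0.822 in the wild-type, 0.699 in the ThPOK-/- and 0.323 in the cKit+ library. Wdfy1, an adaptor of toll-like receptor signalling, was higher in the ThPOK-/- library than in both wild-type libraries of its gate in all 12 types, and over all cells had 47.7 in the ThPOK-/- library, 35.7 in the wild-type GFP, 15.5 in the wild-type and 13.9 in the cKit+ library. On the cell surface, I-A/I-E (MHC class II) was lower past the size rule in the ThPOK-/- library in 4 types and CD38, CD55 and CD86 in 3 each, and NK1.1 was higher in 6.

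A targeted allele may carry a segment of another mouse strain with it, which would show as genes around Zbtb7b that differ more than others. The test covered 117 genes within 10000000 bases. Their mean size of log2 ratio lay at the 30.1 percentile of random sets against the wild-type library. Against the wild-type GFP library it lay at the 78.6 percentile, so no such excess was seen among these genes. S100a8 and S100a9 lie in this window but were not among the 117, with up to 88.8% and 93.6% of entries stored as 0. Over all cells they had log2 ratios of -1.28 and -1.41 against the wild-type library, beyond the largest size among the 117 (1.21, Fmo5). The result therefore does not cover S100a8 and S100a9, which belong to the late granule list.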
